A study of Mus musculus with 6 samples.

How the data were processed

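Total RNA from cultured neonatal mouse cardiomyocytes was labelled with a single dye (Cyanine-3) as amplified cRNA and hybridised to a mouse piRNA microarray, 1 sample per array, per the labels' protocols. PIWI-interacting RNAs (piRNAs) are short RNAs that associate with PIWI proteins and are best known from the germ line. The 6 samples fall into 2 groups of 3, untreated cells and cells given high glucose with palmitate. Groups and replicate numbers were taken from the sample titles. The scanner files themselves are named with numbers 2 to 4 where the titles have 1 to 3, and each file's sample was taken from the series record. Nothing in the labels says whether replicates came from separate cultures or litters, so p-values measure only the spread between these samples, which may be technical.

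The scanner files hold intensity values written by Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed intensity is a spot's brightness after background subtraction and detrending by that software, with no scaling between arrays, per the file headers. Median spot and local background intensities and 0 or 1 flags for spots well above background were also deposited. Each array carries 42486 spots, of which 41069 are piRNA probes present once each. A table of log2 values was also deposited by the authors for 39394 of these probes. Its scale, steps and filter are not stated. It differed by at most 0.10 from quantile normalization of the log2 processed intensities done here over all probes, its column medians were 6.73 on all 6 arrays, and each column correlated with its own array's scanner values at 0.986 or above. Its direction and log base therefore matched the scanner values, and values were not centred per probe. All its probes were well above background on at least 1 array, and 1668 of the 1675 probes it lacks were so on none.

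Probes are identified in these files by the array design's own ID alone. The files do not pair these IDs with piRNA names, sequences or genome positions, and the gene table at hand holds no such ID. The lists fixed beforehand (piRNAs by sequence class, by genomic cluster, by host genes of cardiomyocyte contraction, fuel metabolism, stress and cell death, cell cycle, ribosomal proteins and histones, and by marker genes of fibroblasts, endothelium, smooth muscle and blood cells) were therefore not analysed here, and neither was a piRNA selected by name. No list test was run.

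The main values were log2 processed intensities minus each array's 75th percentile over all piRNA probes, which were used because 77.9% or more of the probes were well above background on every array. Spots with a non-uniformity or population flag (1 to 70 per array) were left out, and no spot was saturated. Probes well above background on all 3 arrays of at least 1 group were tested, 33569 in all. The test was limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Fold changes are treated over untreated. Per-array quantities were compared with exact permutation tests, which cannot go below p = 0.1 for 3 against 3. For a probe not well above background on any array of a group, a bound was computed from the bright group's mean and, per dim array, the higher of the probe's own value and the lowest signal well above background. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.34.

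The scan record and array positions show that 4 arrays (the 3 untreated ones and treated replicate 1) shared slide 1 and that treated replicates 2 and 3 were on slide 2. Slide was fitted as a fixed block as an alternative, which leaves the treatment term to treated replicate 1 against the untreated arrays. The replicate number was fitted as a block too, also as an alternative, because the labels give only a number. The other alternatives were normexp background correction (offset 50), quantile, median and no scaling, another base for the percentile, the authors' table, 3 other filters, flagged spots kept, a trended robust variance, array weights, fold thresholds and leaving out each replicate. Normexp was planned on mean spot intensities and run on median ones, the spot column at hand. The alternatives and the main design were chosen before the data were examined, except cyclic loess, the fit to slide 1 alone, the fit without treated replicate 1 and untreated replicate 3, the slide block with quantile normalization, the counts of probes detected in 1 group only without each array, and the brightness quintiles with their alternatives, which were chosen after seeing the data.

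Probes were named by a rule set beforehand. Where no probe passed, the 8 with the smallest unadjusted p per direction were taken. They came from probes with non-overlapping groups and signal well above background on all 6 arrays. The rule also covered the 5 brightest probes and the largest bounds. In a departure from the rule, only the first 2 per direction are given by ID, because IDs are not paired with piRNA names. The brightest probes and the largest bounds are given as values. The test was checked on simulated data with the spread of these arrays. Among 33569 probes, 50 each carried a known change of 2-, 4-, 8- and 16-fold. With the spread as grouped, 0 of 50 2-fold, 22 of 50 4-fold, 29 of 50 8-fold and 39 of 50 16-fold changes were called, with 4 false calls. The simulated arrays varied independently and shared no slide effect. The counts therefore do not describe the test on these arrays, where slide and treatment go partly together.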

Results

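The series profiled piRNAs in neonatal mouse cardiomyocytes with and without exposure to high glucose and palmitate, a saturated fatty acid. The labels give 40 mM glucose and state the palmitate dose as 300 mM, a unit that is printed as labelled and is open to a slip. The exposure time is not given in the sources used here. Each of the 3 untreated and 3 treated samples was read on 1 array of 41069 piRNA probes. The share of probes well above background was 79.9%, 92.6% and 91.0% on untreated replicates 1, 2 and 3, and 77.9%, 87.7% and 86.1% on treated replicates 1, 2 and 3. The median processed intensity was between 68.7 and 86.5 on the untreated arrays. It was 99.4, 168 and 145 on treated replicates 1, 2 and 3.

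The first question was which piRNA probes gave signal in these cells. On all 6 arrays 29343 probes were well above background, and 1668 were so on none. A probe well above background shows signal at its spot, not that its piRNA was present, because probe specificity was not tested. Detection on all arrays of a group held for 32459 probes in untreated cells and for 30453 in treated cells. The number detected per array was 36077 ± 2843 (SD, n = 3) in untreated and 34460 ± 2170 (SD, n = 3) in treated cells, and the groups overlapped (two-sided exact permutation test, p = 0.5). Signal was uneven over the probes. The 5 brightest averaged 872 to 1111 times their array's 75th percentile, and the adjusted p of their treatment difference was between 0.365 and 0.996 (limma).

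The arrays did not group by treatment. Treated replicates 2 and 3 had the closest profiles of any pair, with a Pearson correlation of 0.984 across the tested probes. Treated replicate 1 correlated at 0.817 and 0.773 with those 2, and at 0.957, 0.973 and 0.832 with untreated replicates 1, 2 and 3. Untreated replicate 3 correlated at 0.871 and 0.861 with untreated replicates 1 and 2, which correlated with each other at 0.976. Probes are not independent replicates, so these coefficients describe the arrays only. The first principal component held 62.7% of the variance and separated treated replicates 2 and 3 from the other 4 arrays. The second held 26.7% and separated untreated replicate 3. Treated replicates 2 and 3 shared slide 2, and the other 4 arrays shared slide 1.

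**Figure D1:**
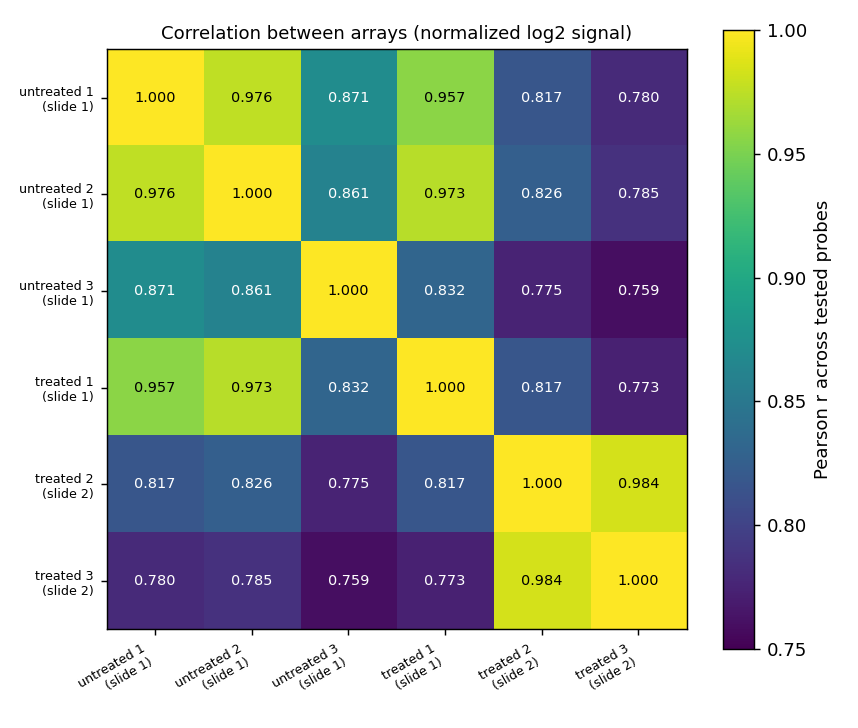
Pearson correlation of normalized log2 signal across the 33569 tested probes for each pair of the 6 arrays, with the slide of each array beside its name; colour and number give r. Treated replicates 2 and 3 correlate at 0.984, and treated replicate 1 lies closer to untreated replicates 1 and 2 (0.957 and 0.973) than to them.

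The main comparison asked which piRNA probes differed between cells given high glucose with palmitate and untreated cells. No probe passed the threshold: 0 of 33569 had an adjusted p under 0.05 in limma's test, and the smallest adjusted p was 0.351. The smallest adjusted p was 0.0695 after quantile normalization, 0.0708 on the authors' deposited values and 0.0821 on unscaled intensities, each with 0 probes under 0.05. At an unadjusted p under 0.05 there were 4500 probes, 1272 of them higher and 3228 lower in treated cells. Of these, 570 were at least 2-fold higher and 2066 at least 2-fold lower. Chance gives 1678 probes at that threshold if the arrays are exchangeable, which these were not. The other groupings of the same arrays into 3 and 3 gave between 13 and 13787 such probes. The excess over 1678 is therefore no measure of a treatment effect. The split between directions rested on the scaling. Quantile normalization gave 2546 higher and 2667 lower, normexp background correction 858 higher and 4004 lower, and unscaled intensities 10681 higher and 330 lower. The median log2 fold change over all tested probes was -0.12 after the 75th percentile scaling and 0.64 without scaling. Group values did not overlap for 1964 higher and 4111 lower probes, together 18.1% of those tested, where chance gives 10% for 3 against 3 exchangeable arrays. These arrays were not exchangeable: where the slide 2 pair already stands apart, treated replicate 1 need only be the extreme one of the 4 slide 1 arrays, which chance gives in 25%.

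With slide as a block the count was again 0, with a smallest adjusted p of 0.654 and 2472 probes at an unadjusted p under 0.05. On slide 1 alone, treated replicate 1 against the 3 untreated arrays gave 0 probes, a smallest adjusted p of 0.875 and 1049 probes at an unadjusted p under 0.05, with the single treated array assumed to vary like the untreated ones. Slide 2 held treated arrays only, so it gives no within-slide comparison. Without treated replicate 1 the same test called 11775 probes, 5079 higher and 6696 lower; the treated arrays were then both on slide 2 and the untreated ones all on slide 1. Within the treated group, treated replicates 2 and 3 on slide 2 against the single treated array on slide 1 gave 7564 probes, 3777 higher and 3787 lower on slide 2. That test takes its spread from the untreated arrays and the slide 2 pair, and assumes that treated replicate 1 varies like them. It cannot tell a slide difference from a deviation of that single array.

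The probe with the smallest unadjusted p was ASPI198606P, which averaged 4.09 ± 0.62 (SD, n = 3) in untreated and 0.46 ± 0.45 (SD, n = 3) in treated cells on the normalized log2 scale. Its log2 fold change was -3.63 with a standard error of 0.40, a 12.4-fold lower mean, and its adjusted p was 0.351 (limma). Its values were 4.06, 3.49 and 4.72 on the untreated arrays and 0.98, 0.29 and 0.12 on the treated ones. With slide as a block its log2 fold change was -3.11, with an adjusted p of 0.654. ASPI317318P had a log2 fold change of -1.80 with a standard error of 0.29, from 0.45 ± 0.43 (SD, n = 3) to -1.36 ± 0.07 (SD, n = 3). The slide block gave -1.76, median scaling -1.86 and unscaled intensities -1.05.

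On the higher side, ASPI356575P had a log2 fold change of 1.90 with a standard error of 0.28, a 3.72-fold higher mean. Its mean was -1.38 ± 0.09 (SD, n = 3) in untreated and 0.51 ± 0.39 (SD, n = 3) in treated cells. ASPI282394P had a log2 fold change of 1.58 with a standard error of 0.24, from -2.08 ± 0.13 (SD, n = 3) to -0.50 ± 0.13 (SD, n = 3). The slide block gave 1.46 and 1.74 for these probes. Normexp background correction gave 1.19 and 0.80, and unscaled intensities 2.65 and 2.34. All 4 probes had an adjusted p of 0.351 in limma's test. They were picked for groups that do not overlap, which by itself fixes their direction in the slide block, on slide 1 alone and without any 1 array. The 8 probes with the smallest unadjusted p on the higher side had log2 fold changes of 1.43 to 1.90, and the 8 on the lower side -3.63 to -1.80. None of the 16 passed the threshold with slide as a block.

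**Figure D2:**
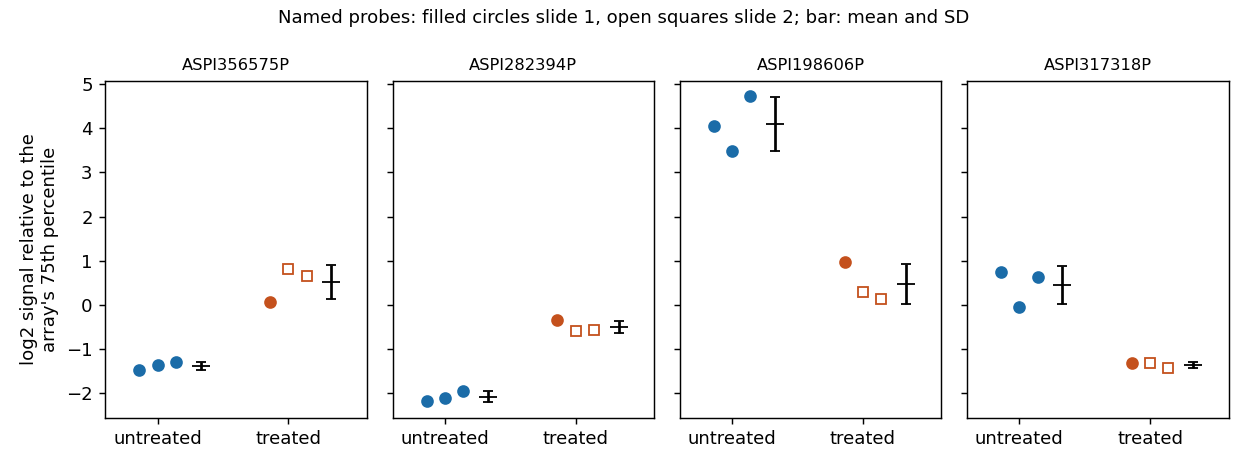
Log2 signal relative to the array's 75th percentile for the 4 named probes, in the 3 untreated (blue) and 3 treated (orange) samples; filled circles are slide 1, open squares slide 2, and the black bar is the group mean with its SD. ASPI198606P is at 3.49 to 4.72 in untreated and 0.12 to 0.98 in treated cells.

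Probes were also compared by brightness, in quintiles of their mean over all 6 arrays, as the median of each quintile relative to the array's median. This grouping was chosen after seeing the data. The brightest quintile, 6714 probes, stood at 2.30 ± 0.30 (SD, n = 3) on untreated and 1.86 ± 0.66 (SD, n = 3) on treated arrays, a difference of -0.44 (two-sided exact permutation test, p = 0.4). The treated arrays were unlike one another, at 2.62, 1.53 and 1.44 for replicates 1, 2 and 3. On slide 1 alone the difference was 0.32, in the opposite direction, and with normexp background correction it was -0.26. Quantile normalization, which gives all arrays the same distribution, holds it near 0 by construction. It was -0.82 without treated replicate 1, -0.27 without treated replicate 2 and -0.23 without treated replicate 3. The dimmest quintile, also 6714 probes, was at -1.05 ± 0.11 (SD, n = 3) on untreated and -1.29 ± 0.09 (SD, n = 3) on treated arrays, which did not overlap (two-sided exact permutation test, p = 0.1, the smallest this design allows). The difference of -0.24 was -0.14 on slide 1 alone and -0.23 with normexp background correction. It was -0.09 after quantile normalization, which narrows it by construction, and -0.09 in the authors' deposited table. Of the probes at an unadjusted p under 0.05, 332 higher and 1331 lower ones were in the dimmest quintile. The brightest held 27 higher and 936 lower ones. Over all tested probes the split between directions rested on the scaling, as above, and these quintile counts were made with the main scaling alone. In the dimmest quintile the filter may add to the excess of lower probes and to the lower treated values. It kept 32459 probes through the untreated arrays and 30453 through the treated ones, 29343 of them through both. A probe kept through 1 group alone tends to be dimmer in the other. Over all tested probes, 71.7% of those at an unadjusted p under 0.05 were lower with this filter. That share was 68.2% among probes well above background on all 6 arrays and 77.1% with no filter. Within the dimmest quintile the filter's part was not tested.

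Detection gave 271 probes well above background on all untreated arrays and on no treated one. The signal in untreated cells was at least 2-fold higher for 61 of them, and the median bound was 1.71-fold. The 3 largest bounds were 4.43-, 3.94- and 3.38-fold. In the other direction 31 probes were well above background on all treated and no untreated array. Of these 12 were at least 2-fold higher in treated cells, with a median bound of 1.93-fold and largest bounds of 2.81-, 2.58- and 2.56-fold. None of the probes in either set passed limma's test. The bounds rest on the scaling and were computed with that one alone. The 75th percentile of processed intensity was 144, 172 and 138 on untreated replicates 1, 2 and 3. It was 214, 299 and 258 on treated replicates 1, 2 and 3. Unscaled bounds would therefore be smaller for the first set and larger for the second. The counts moved with single arrays. Without treated replicate 1 they were 953 and 518, and without untreated replicate 1 the first was 1273. Without untreated replicate 2 or 3 the second was 99 or 62.

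Signal at control probes also differed between the slides. The array carries 10 probes for E1A spike-in transcripts, which are adenoviral and have no counterpart in mouse RNA, each on 32 spots. Whether spike-in RNA was added is not given in the sources used here. Both slide 2 arrays lay above every slide 1 array for 6 of the 10 probes and below for 2. The difference between slides ranged from -0.73 to 1.39 on the normalized log2 scale. For the probe E1A_r60_a97 the slide 1 values were -1.58 to -0.94, with treated replicate 1 at -1.58, and the slide 2 values were 0.04 and 0.11.

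**Figure D3:**
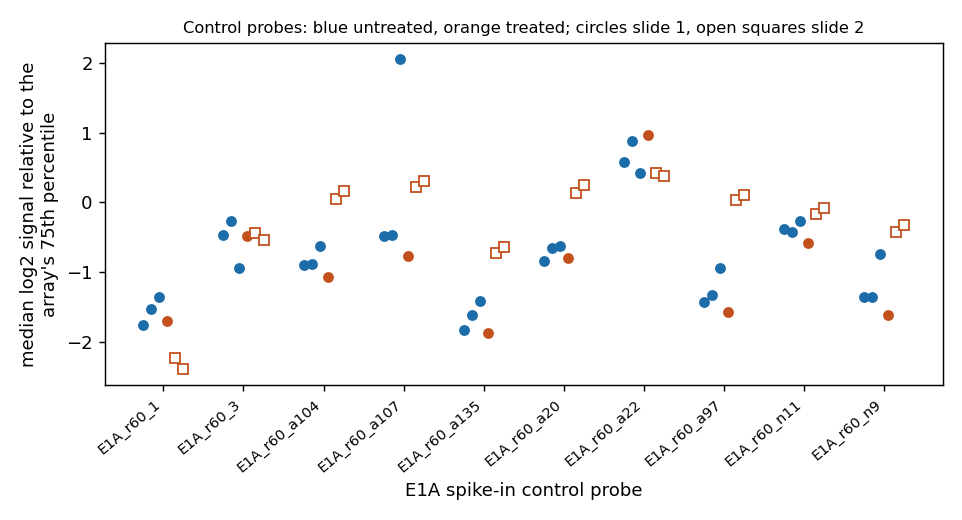
Median log2 signal over 32 spots, relative to the array's 75th percentile of piRNA probes, for the 10 E1A spike-in control probes; blue is untreated, orange treated, filled circles slide 1 and open squares slide 2. Both slide 2 arrays lie above all slide 1 arrays for 6 probes and below them for 2.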

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

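The tests of explanations in this part were all chosen after the results were seen, except the count of other splits at the adjusted threshold, which was planned. For 4 of the 10 E1A spike-in probes the treated mean exceeded every untreated array, a signal in control spots that the comparison of piRNAs does not use. Treated replicate 1 exceeded every untreated array for 1 of the 10.

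Treated replicates 2 and 3 stood apart from the other 4 arrays. The treatment alone, carried alike by all 3 treated arrays, is argued against. With separate untreated arrays on each side, treated replicate 1's differences were set against those of replicates 2 and 3. The slope was 0.0456, 0.0169 and -0.323 with untreated replicates 1, 2 and 3 in turn. It was 0.55 to 0.92 for replicate 2 on replicate 3, but those arrays share slide 2, which by itself can raise their slope. A hybridization or scan difference between slides stays open. The slide shift had an SD of 0.68 over the E1A probes. Sets of piRNA probes matched for brightness gave 0.47 to 1.21 (95% of 10000 draws). These values cannot place the cause in hybridization or scan. Without added spike-in RNA, signal at the E1A probes would come from the samples themselves. A wrong label on treated replicate 1 stays open too: its mean correlation with the untreated arrays was 0.921, and that of untreated replicates 1, 2 and 3 with their own group was 0.924, 0.918 and 0.866. These means cover unlike sets, because untreated replicate 3 weighs less in that of treated replicate 1. Pair by pair, treated replicate 1 correlated at 0.957, 0.973 and 0.832 with untreated replicates 1, 2 and 3. Untreated replicates 1 and 2 correlated at 0.976 with each other, and at 0.871 and 0.861 with untreated replicate 3. A treatment effect in replicates 2 and 3 stays open as well, because slide 2 holds no untreated array.

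Untreated replicate 3 stood apart within its group. A brightness-dependent trend of that array is argued against as the whole cause, since the gap between its correlation with replicates 1 and 2 and theirs with each other was 0.109 before and 0.0887 after cyclic loess. No biological explanation was tested.

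Of the 10 splits of the 6 arrays into 3 and 3, all 10 gave at least the real count at an adjusted p under 0.05, which says nothing because that count is 0; the highest other split gave 6131. At an unadjusted p under 0.05, 2 of the 10 splits reached the real count of 4500, the other being 13787. With 10 splits no share under 0.05 can occur. The split with the highest counts set untreated replicates 1 and 2 and treated replicate 1 against the rest. What sets that split was not tested.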

How the results depend on the processing

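The count of probes at an adjusted p under 0.05 stayed at 0 under 22 of the 26 alternatives, including every scaling, background correction and filter, the authors' table, and the slide and replicate blocks. For 1 of the 22, the adjusted threshold with 2-fold added, this was fixed, since it only narrows a count of 0. The count was 22747 with array weights, which gave treated replicate 1 a weight of 0.082 against 6.71 for treated replicate 2. It was 21434 without treated replicate 1 and untreated replicate 3, and 2636 at the looser threshold of an unadjusted p under 0.05 and 2-fold. Leaving out 1 array gave 0 to 11775, and 0 for every array but treated replicate 1. Apart from the looser threshold, the settings with calls were those that left out or down-weighted treated replicate 1, so that the treated arm rested on slide 2. At an unadjusted p under 0.05 the count ran from 1327 without treated replicate 2 to 15937 without treated replicate 1, was 11011 unscaled, 1049 on slide 1 alone, and 23773 with array weights. The replicate block gave 5483 there. Same-numbered samples deviated together for replicates 1 (r = 0.36) and 3 (0.46) but not 2 (-0.29). Unlike-numbered ones did so for untreated 2 with treated 1 (0.37) and untreated 3 with treated 2 (0.36). The remaining unlike-numbered pairs were at -0.44 to -0.30. Deviations cancel out within a group, and treated replicate 1 and untreated replicate 3 each stood apart in theirs, so these values cannot test pairing. The numbers were not taken as pairs because the labels give only a number. The brightest quintile's difference of -0.44 turned to 0.32 on slide 1 alone; the cause was not tested. The 4 named probes kept their direction in all 24 alternatives, which their selection fixes in part. The other filters, the trended robust variance and the replicate block cannot turn it, since they left the fold changes of these probes as they were. Their log2 fold changes were -3.93 to -2.87, -2.05 to -1.05, 1.19 to 2.65 and 0.80 to 2.34 (ASPI198606P, ASPI317318P, ASPI356575P, ASPI282394P), and each passed the threshold in 3 settings, all of which left out or down-weighted treated replicate 1. Detected probes per group stayed within 1.5 times under looser detection. The list tests, genomic clusters and their alternatives were not run, for lack of probe identities. On simulated data with the within-slide spread, 8 of 50 2-fold and 33 of 50 4-fold changes were called. That run had no slide effect and no slide block, a comparison that these arrays do not offer.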

Other observations

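The tests in this part were chosen after the data were seen. Of the 11775 probes called without treated replicate 1, that array lay beyond the untreated range on the same side as the other treated arrays for 3398 (28.9%), where an array exchangeable with the untreated ones would do so for 25%. That share is raised by the way the probes were chosen, since the untreated arrays were selected to lie far from treated replicates 2 and 3.

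Untreated replicate 3 read 2.06 at the control probe E1A_r60_a107, where the other 5 arrays read -0.76 to 0.31.

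If probe ID numbers followed genomic order, neighbours might share a level, because piRNAs of a cluster share a precursor. The correlation across probes between the mean signals of the 4179 pairs with consecutive numbers was -0.00036 (permutation test, two-sided, p = 0.98). Probes differ in affinity, which can hide a shared level, so the question stays open.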
